A study of Mus musculus with 18 samples.

How the data were processed

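RNA from the scraped epidermis of single mice or pools (the labels do not say which) was sequenced in 18 libraries of 6 groups, by genotype (WT, OPN-null, K14-OPN) and UVB exposure. The labels name the molecule as polyA RNA and describe male mice of 10 weeks, shaved 48 h before 180 mJ per cm2 of UVB and sampled 24 h after it. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

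The values used are whole-number counts of reads per gene, deposited by the authors in 1 table without normalization. The submitters' processing notes name bcl2fastq 2.18.0.12, Trim Galore 0.6.5, STAR 2.7.5a, HTSeq 0.11.3 and the build GRCm38, without their role or order. The annotation release, the counting mode and the use of strand are not given in the sources used here, so overlapping genes on either strand may share or lose reads. One such case is Gm42793, a gene that overlaps the start of Spp1 on the same strand. The table held 56246 genes, of which 55144 were matched by identifier to a symbol in GENCODE release M21, and 5 summary lines of the counting program that name no gene. Those lines were left out of library sizes and tests. As shares of all reads in the table, reads outside any gene were 20.75 to 50.36%, ambiguous reads 2.507 to 13.87% and reads with several alignments 12.1 to 29.25%, and gene counts were 11.22 to 55.97%. Every per-sample column was used.

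Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18910, and libraries were scaled by TMM. One quasi-likelihood model with the 6 group means was fitted to all 18 libraries, because groups of 2 to 4 share 1 estimate of spread. The 11 contrasts were the UVB response in each genotype, the 3 genotype differences after and without UVB, and the difference of the UVB response of WT and of K14-OPN from that of OPN-null. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes of a contrast. All tests are two-sided. Fold changes are log2 with standard errors from the fit and a prior count of 0.125, and log2 CPM uses a prior count of 2 and TMM-scaled sizes. Where a group had no count, the fold was bounded by a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval is given. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

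A set of 33 gene lists (keratinocyte states, stress and immune responses, other cell types of skin, neighbours of Spp1, and RNA quality), the groups, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with limma camera on voom values at a preset correlation of 0.01, adjusted over the 33 lists of a contrast, and again with an estimated correlation. The named genes are Spp1, the 6 highest and 6 lowest fold changes among called genes of the main contrasts (3 and 3 in the others) with an absolute log2 fold change of at least 1, a mean log2 CPM of at least 1, no overlap of the groups and a named, non-clone, non-immunoglobulin symbol, and up to 4 members of each described list by smallest p. Genes named as members of a group of 5 or fewer, the 17 genes called in all genotypes, and the genes called by single alternatives were otherwise chosen after their values were seen, as were the permutation tests of list means.

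Library kind (7SK-rich or Lars2-rich) was read from Rn7sk and Lars2 counts, which the labels do not mention. Each group held exactly 1 7SK-rich library among its 2 to 4, so the share of that kind differs between groups. Pooled contrasts can therefore carry part of the difference between kinds. The planned model was kept, and within-kind values are printed. The biological coefficient of variation was 0.816 in the planned model and 0.595 with library kind as a term. The median correlation of log2 CPM across genes was 0.92 for 7 pairs of the same group and kind and 0.833 for 12 pairs of the same group and different kind. No pair of libraries agreed within sampling noise, so all 18 were counted separately. K14-OPN libraries with and without UVB share the numbers 1 and 2 in their labels, which do not say what the number marks, so the planned model has no block.

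The alternatives fixed in advance were RLE scaling, DESeq2, no filter on low counts, a fit of the compared groups only, the mean of the dermal fibroblast list as a covariate, limma with quality weights, a replicate block, and leaving out each library in turn. Chosen after seeing the data were library kind as a term, the Lars2-rich libraries only, and leaving out 3 unirradiated libraries that stood apart in hair genes or complexity (WT 10, K14-OPN 11 and OPN-null 9), alone or with library kind. The model was tested on simulated counts with 200 genes changed 2, 4 or 8-fold in the UVB response, at the spread of the planned model. It recovered 0, 0 and 4.55% of them in WT, 0, 1.49 and 21.2% in OPN-null and 0, 2.99 and 40.9% in K14-OPN, with 0, 1 and 1 false calls. At the spread found with library kind as a term, the planned model recovered 59.1, 68.2 and 78.8% of 8-fold changes. The simulated counts held no difference between library kinds, and genes were drawn independently. The false calls therefore leave out any that library kind or deviations shared within a library would add. Pathway classification with PANTHER, named in the stated aims, was not run here, and similarity was examined through fold changes across genes.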

Results

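Epidermis was scraped from the back skin of 10-week-old male mice of 3 genotypes, either 24 h after one UVB exposure of 180 mJ per cm2 or without exposure. Its RNA was sequenced in 18 libraries. Osteopontin (OPN) is a secreted phosphoprotein that binds integrins and CD44 and is encoded by Spp1. The genotypes were wild type (WT), OPN-null, and K14-OPN, in which the keratin 14 promoter of basal keratinocytes drives OPN on the OPN-null background. Without UVB there were 2 WT, 3 OPN-null and 3 K14-OPN libraries, and after UVB 3 WT, 4 OPN-null and 3 K14-OPN libraries. A library is named here by its group and the number in its label. Reads counted to genes ranged from 3696865 to 26068614 per library (median 10680000), and between 12874 and 25483 genes had a count. The stated aims were to check OPN expression from the transgene, to compare it with WT and OPN-null with and without UVB, and to ask whether K14-OPN and WT differ from OPN-null in a similar way after UVB.

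The libraries fell into 2 kinds that the labels do not name. In 6 libraries, exactly 1 in each group, the small nuclear RNA Rn7sk had 66654 to 383142 counts and Lars2 1216 to 6763. In the other 12 libraries Rn7sk had 295 to 2904 counts and Lars2 149186 to 822109. They are called 7SK-rich and Lars2-rich. A total of 7927 of 18910 genes passed the test between the kinds, 4955 higher and 2972 lower in the 7SK-rich libraries. Because each group held 1 7SK-rich library among its 2 to 4, the share of that kind differs between groups. Within-kind values are therefore given beside the pooled ones, a 7SK-rich value being 1 library against 1. In OPN-null 9, without UVB, 10 genes took 84.26% of the counts, the highest share of the 18 libraries. Among Lars2-rich libraries, on which the UVB responses largely rest, this share was 37.49 to 84.26% in the 5 unirradiated and 12.43 to 37.13% in the 7 irradiated ones. Their library sizes after TMM scaling were 1404294 to 9585098 and 6586470 to 36682175. The first principal component held 29.2% of the variance and the second 22.8%.

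**Figure D1:**
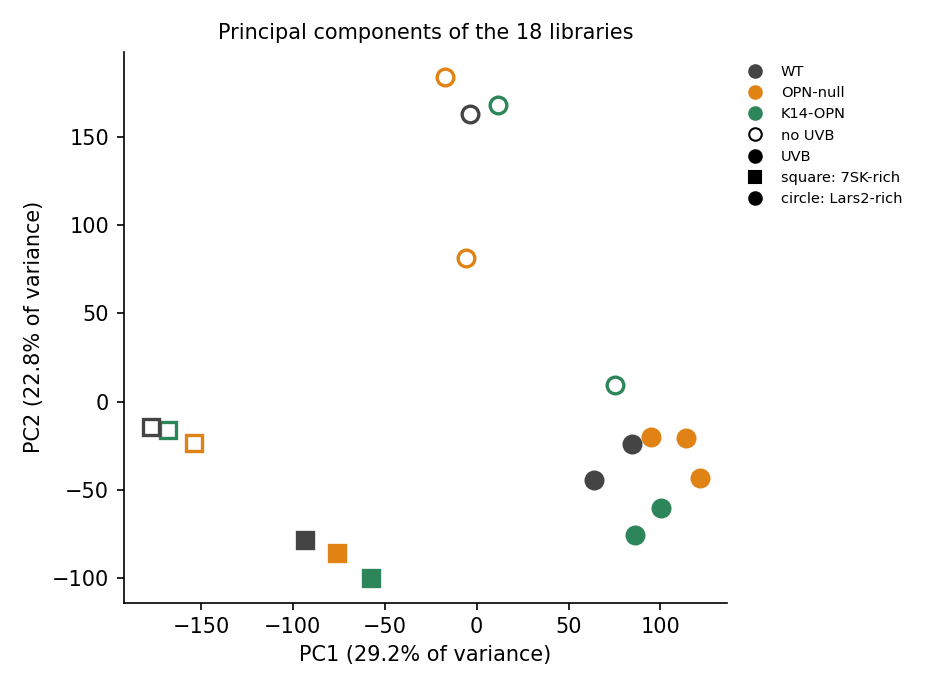
First and second principal components (29.2% and 22.8% of the variance) of log2 CPM over the tested genes. Each point is a library, coloured by genotype, filled after UVB and open without it. Squares are the 6 7SK-rich and circles the 12 Lars2-rich libraries.

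Spp1 (ENSMUSG00000029304.14, GRCm38 chromosome 5, 104435118 to 104441050, plus strand) was low in OPN-null epidermis, at 2.10 ± 1.89 CPM (the read count scaled to library size; SD, n = 3) without UVB and 3.46 ± 2.77 (n = 4) after UVB. Its counts there were 0 to 74 per library. In K14-OPN it was at 54.5 ± 18.3 CPM (n = 3) without and 477 ± 244 CPM (n = 3) after UVB, and in WT at 23.9 ± 30.1 (n = 2) and 224 ± 191 CPM (n = 3). After UVB, Spp1 was higher than in OPN-null by a log2 fold change of 7.11 ± 1.15 (SE; 138-fold) in K14-OPN and 6.02 ± 1.10 (64.8-fold) in WT. The libraries did not overlap (exact two-sided permutation p = 0.0286 for each, the smallest that 35 assignments give). K14-OPN and WT differed by 1.09 ± 1.01 after UVB and by 1.22 ± 1.18 without (exact permutation p = 0.3 and 0.2). Without UVB, K14-OPN exceeded OPN-null by 4.49 ± 1.19 (exact permutation p = 0.1, the smallest that 20 assignments give). WT exceeded it by 3.27 ± 1.21, with overlapping libraries (exact permutation p = 0.5) and a value of 0.08 without WT 10.

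After UVB, Spp1 was higher than without it by 3.25 ± 1.30 in WT and 3.13 ± 1.08 in K14-OPN, with edgeR p of 0.0338 and 0.0232 adjusted over the 9 comparisons of this gene. The WT value was 6.53 without WT 10 and 2.32 without WT 11, the range over fits without 1 WT library. By exact permutation p was 0.3 in WT, where the libraries overlapped, and 0.1 in K14-OPN, the smallest that 20 assignments give. In OPN-null the value was 0.50 ± 1.03 (adjusted p = 0.632). The same adjustment gave 9.18e-05 for K14-OPN and 0.000186 for WT against OPN-null after UVB, and 0.00474 and 0.0268 without UVB. None of these 9 comparisons passed once p was adjusted over all 18910 genes (adjusted p of 0.156 or more). The 3 UVB differences in WT, OPN-null and K14-OPN were 2.32, −0.95 and 3.43 in the 7SK-rich libraries and 2.84, 2.43 and 2.90 in the Lars2-rich ones. After UVB the excess over OPN-null was 8.59 (7SK-rich) and 6.6 (Lars2-rich) in K14-OPN and 2.77 and 6.54 in WT. K14-OPN exceeded WT by 5.83 and 0.06. Without UVB the corresponding values were 4.21 and 6.13 for K14-OPN against OPN-null, −0.50 and 6.14 for WT against OPN-null, and 4.72 and 0 for K14-OPN against WT. In unirradiated OPN-null, 74 of the 80 Spp1 counts were in the 7SK-rich library. The Lars2-rich values that use this group (2.43, 6.13 and 6.14) thus rest on near-zero counts, and their size depends on the prior count. The Lars2-rich side of unirradiated WT was 1 library, WT 10. Because a table of whole genes does not show which part of Spp1 was read, the counts left in OPN-null cannot be placed within the gene.

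**Figure D2:**
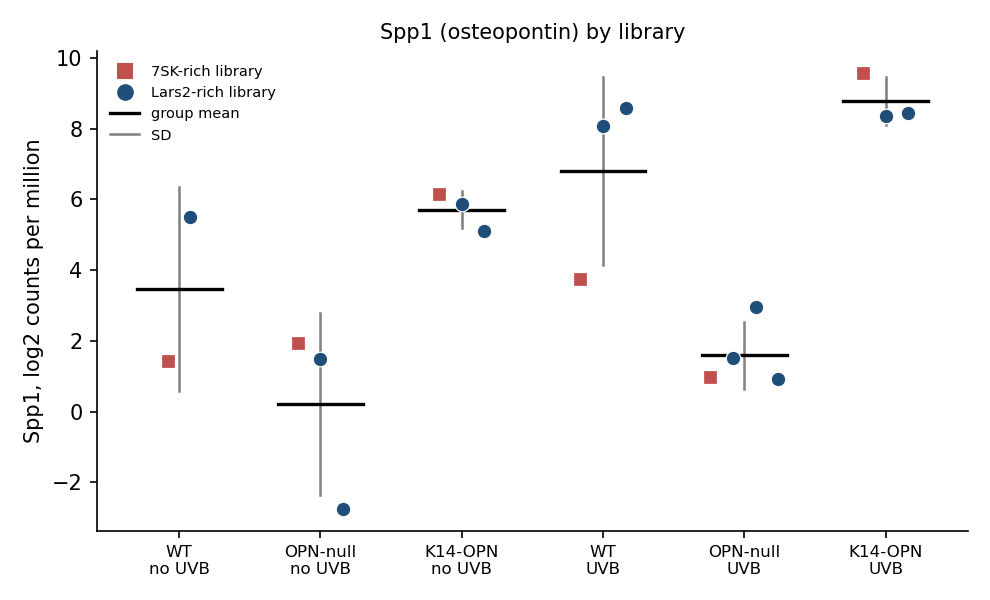
Spp1 in each library as log2 CPM by genotype and UVB exposure. Squares are 7SK-rich and circles Lars2-rich libraries, with a black line at the group mean and a grey bar of 1 SD on each side. OPN-null libraries averaged 2.10 and 3.46 CPM, K14-OPN libraries 54.5 and 477 CPM.

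Across genotypes, 17 genes passed the test of the UVB response in all 3, each in the same direction: Ccng1, Med10, Stom, Tinagl1, Epgn, Lgi2, Ier5l, Rela, Robo3, Cd81, Ptp4a3, Wincr1, Calcoco1, Ankrd44, Fam189a2, Apcdd1 and Plcxd2. Of the 18 genes called in WT, all 18 were called in OPN-null (0.315 expected of independent lists) and 17 in K14-OPN (0.0939 expected). OPN-null and K14-OPN shared 133 genes (3.39 expected), and no shared gene had opposite signs. The 3 tests share 1 fit with 1 estimate of spread per gene, so the lists are not independent and these expected numbers may be too low. Across genes, which are not independent replicates, the fold changes of the genotypes correlated with r = 0.577 between WT and OPN-null, 0.728 between WT and K14-OPN and 0.509 between OPN-null and K14-OPN. Unirradiated WT and K14-OPN each held 1 library high in hair shaft genes, WT 10 and K14-OPN 11. The median UVB log2 fold change of those genes was −12 in WT, −7.36 in K14-OPN and −1.45 in OPN-null. These libraries can raise the r between WT and K14-OPN, which was not computed without them. With library kind as a term, 413 genes were called in all 3 genotypes.

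The UVB response of OPN-null epidermis (4 irradiated and 3 unirradiated libraries) held 350 genes that rose and 294 that fell, and with library kind as a term 1365 and 1229. Lgi2, a secreted leucine-rich repeat protein, was at least 233-fold higher (adjusted p = 0.00312, bounded by a floor of 3 counts over the group). Hmga2, a chromatin protein, had 159 times its unirradiated level (95% counting interval 54.2 to 772, adjusted p = 0.0209). The cytokine gene Il24 rose by 6.96 ± 1.46 and the wound keratins Krt6b and Krt6a by 6.63 ± 1.57 and 6.32 ± 1.33 (adjusted p = 0.0167, 0.0293 and 0.0167). Phkg1, a subunit of phosphorylase kinase, rose by 6.13 ± 0.938 (adjusted p = 0.00497). Skint7, of a family expressed in skin and thymic epithelium, changed by −6.00 ± 0.693, the procollagen protease Adamts14 by −5.00 ± 1.03 and the collagen gene Col5a1 by −4.92 ± 0.834. The kinase genes Stk10 and Nuak1 changed by −4.67 ± 0.808 and −4.60 ± 0.571 and Dab1 by −4.61 ± 0.959 (adjusted p of these 6 from 0.00106 to 0.0162).

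Of 28 p53 targets in OPN-null, 15 rose, 1 fell and 12 did not pass, or 17 and 1 adjusted over the list alone. Cyclin G1 (Ccng1) rose by 3.30 ± 0.533, the death receptor gene Tnfrsf10b by 3.60 ± 0.637, the DNA polymerase gene Polk by 2.68 ± 0.454 and the cell cycle inhibitor Cdkn1a by 2.52 ± 0.447 (adjusted p = 0.00555, 0.008, 0.00672 and 0.008). The member that fell was Sesn1 (−2.11 ± 0.522, adjusted p = 0.0354). The list rose in camera (adjusted p = 2.71e-12, and adjusted p = 0.0502 with an estimated correlation). Of 29 wound and hyperproliferation keratinocyte genes, 7 rose and 22 did not pass, or 26 rose adjusted over the list alone. Krt16 was at 4.81 ± 1.09 and Sprr2f at 5.46 ± 1.27 (adjusted p = 0.0238 and 0.0271). All 29 fold changes were positive, with a median of 4.59 (4.55 with near-zero members at their bound; camera adjusted p = 7.1e-17, and adjusted p = 0.411 with an estimated correlation). Among 21 EGFR ligands and immediate early genes, 4 rose and 1 fell, or 8 and 1 adjusted over the list alone. Epgn (5.30 ± 0.700), Hbegf (4.24 ± 1.04) and Areg (3.88 ± 0.815), which encode EGFR ligands, and the phosphatase gene Dusp6 (3.09 ± 0.538) rose, and the ligand gene Btc changed by −4.55 ± 0.826 (adjusted p of 0.0342 or less). Camera gave 7.19e-07, and adjusted p = 0.0983 with an estimated correlation. All 25 cytokine and chemokine genes had positive fold changes and 1, Il24, passed. Adjusted over the list alone Il24, Il19, Il33 and Ccl20 passed (camera 3.91e-07, and adjusted p = 0.495 with an estimated correlation).

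Of 26 cornified envelope genes in OPN-null, 3 fell and 23 did not pass: Kprp (−2.08 ± 0.482), Lce1l (−2.81 ± 0.717) and Lce1m (−3.02 ± 0.811), with adjusted p of 0.0263, 0.0408 and 0.0497. Adjusted over the list alone 12 fell and 3 rose (camera 0.00481, and adjusted p = 0.538 with an estimated correlation). Of 16 dermal fibroblast genes, 5 fell, or 7 adjusted over the list alone. The 5 were Col5a1, Col1a1 (−4.39 ± 1.07, adjusted p = 0.0335), Col6a1 (−3.07 ± 0.572, 0.00933), Col6a2 (−2.70 ± 0.604, 0.0219) and Fbn1 (−3.24 ± 0.833, 0.0418). The list fell in camera (adjusted p = 3.91e-07, and adjusted p = 0.45 with an estimated correlation). The mean of that list was 5.26 ± 0.301 log2 CPM (SD, n = 3) without UVB and 2.45 ± 1.52 (n = 4) after it. Of 17 circadian clock genes, Hlf (−3.41 ± 0.688, adjusted p = 0.0151) and Per3 (−2.75 ± 0.581, 0.0175) fell and Bhlhe40 rose (1.69 ± 0.436, 0.0419). Adjusted over the list alone 5 fell and 2 rose (camera 0.019, and adjusted p = 0.538 with an estimated correlation). Among nucleotide excision repair genes Ercc1 (1.79 ± 0.434, adjusted p = 0.033) and Ercc5 (1.13 ± 0.291, 0.0413) rose, 2 of 18 also adjusted over the list alone. The list did not pass (camera 0.171). In the Lars2-rich libraries alone 1913 genes were called, of which 1778 (92.9%) had the same sign in the 7SK-rich pair, against 67.5% of all genes. With the dermal fibroblast mean as a covariate 25 genes were called. The count was 340, 219, 237, 200 and 242 without OPN-null UVB 13, 14 or 15 or unirradiated OPN-null 8 or 9.

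In WT (3 irradiated and 2 unirradiated libraries), 12 genes rose after UVB and 6 fell. Lgi2 was at least 220-fold higher (no count in unirradiated WT, adjusted p = 0.0247). The basement membrane protein gene Tinagl1 rose by 5.57 ± 0.967, Stom, a membrane scaffold protein, by 4.59 ± 0.844, Ccng1 by 4.58 ± 0.690, Epgn by 4.37 ± 0.799 and Ier5l by 3.32 ± 0.541 (adjusted p from 0.0247 to 0.0467). The 6 that fell were Tbc1d9 (−3.60 ± 0.650), Plcxd2 (−3.58 ± 0.635), Ankrd44 (−3.27 ± 0.516), the WNT inhibitor gene Apcdd1 (−2.97 ± 0.489), Calcoco1 (−2.91 ± 0.527) and Fam189a2 (−2.70 ± 0.412), with adjusted p from 0.0247 to 0.0467. Of 28 p53 targets 1, Ccng1, rose and 27 did not pass, but 17 rose and 1 (Sesn1) fell adjusted over the list alone. The list rose in camera (median 1.81, adjusted p = 8.08e-18, and adjusted p = 0.0111 with an estimated correlation). Of all camera calls over the 11 comparisons, 1 held with an estimated correlation, this one, and with library kind as a term none did (adjusted p = 0.0723 for this list).

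None of the 29 wound keratinocyte genes passed in WT, and 7 did adjusted over the list alone, among them Krt16, Krt6a, Krt6b and Defb3. All 29 fold changes were positive, with a median of 3.23 (camera 1.17e-17, and adjusted p = 0.29 with an estimated correlation). The 25 cytokine and chemokine genes also all had positive fold changes and none passed. Adjusted over the list alone 4 passed, Il33, Ccl20, Il24 and Cxcl5 (camera 5.66e-09, and adjusted p = 0.462 with an estimated correlation). Of 15 basal keratinocyte genes none passed and 1, the integrin gene Itgb1 (2.17 ± 0.522, adjusted p = 0.093), did adjusted over the list alone (camera 9.17e-06, and adjusted p = 0.29 with an estimated correlation). Hair shaft genes were negative for 23 of 23 members in WT, 23 passing adjusted over the list alone and none over all genes (camera 0.00124, and adjusted p = 0.676 with an estimated correlation). They had a mean of 5.94 ± 7.53 log2 CPM (SD, n = 2) without UVB (11.3 in WT 10) and 0.313 ± 0.210 (n = 3) after it. Without WT 10, K14-OPN 11 and OPN-null 9, which stood apart in hair genes or complexity, the adjusted p of that list was 0.769. In the edgeR fit of all libraries 2463 genes in WT had an unadjusted p below 0.05. No gene was called by edgeR without any 1 of the 5 WT libraries or in the Lars2-rich libraries alone. The Lars2-rich fit and those without WT 10 or WT 11 hold 1 unirradiated WT library, which is assumed to vary like the other groups. In a fit of the 5 WT libraries alone none was called either (1984 at an unadjusted p below 0.05). Without the 3 libraries that stood apart 1 gene (Lgi2) was called, and with library kind as a term 705.

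UVB changed 200 genes in K14-OPN (n = 3 and 3), 96 rising and 104 falling, and with library kind as a term 1458 (620 and 838). In an edgeR fit of these 6 libraries alone no gene was called (2208 at an unadjusted p below 0.05). Lgi2 rose by 6.51 ± 0.915, the antimicrobial peptide gene Defb3 by 5.98 ± 1.38, and the matrix protein gene Spon2 by 5.67 ± 1.23. The glutathione transferase gene Gsta4 rose by 5.20 ± 1.12, the p53 target Eda2r by 5.11 ± 1.05 and Epgn by 5.03 ± 0.691 (adjusted p of these 6 from 0.00494 to 0.0456). The metallothionein gene Mt4 changed by −8.75 ± 1.87, the amino acid transporter gene Slc38a3 by −6.46 ± 1.41, and Adamts14 by −5.23 ± 1.17. The carbonic anhydrase gene Car6 changed by −4.96 ± 1.06, Nuak1 by −4.89 ± 0.651 and the steroid dehydrogenase gene Hsd17b14 by −4.86 ± 0.961 (adjusted p of these 6 from 0.0044 to 0.0396). Mt4 was at 513 ± 756 CPM (SD, n = 3) without UVB. Without unirradiated K14-OPN 11, Mt4, Slc38a3, Car6 and Hsd17b14 were at −6.02, −5.3, −3.28 and −3.37 and did not pass (adjusted p of 0.0732 to 0.105). Nuak1 passed in each fit without 1 of the 3 irradiated libraries, and the other 5 in none of them. Of 28 p53 targets 5 rose and 23 did not pass (Ccng1 3.53 ± 0.549, Tnfrsf10b 3.32 ± 0.631, Eda2r, Polk 2.12 ± 0.454 and Plk2 2.15 ± 0.479). Adjusted over the list alone 16 rose and 1 fell (camera 1.35e-11, and adjusted p = 0.0729 with an estimated correlation). Of 15 basal keratinocyte genes 2 rose, Itgb1 (2.57 ± 0.454, adjusted p = 0.0147) and Itga3 (3.09 ± 0.702, 0.0432). Adjusted over the list alone 9 rose and 1 fell (camera 2.16e-07, and adjusted p = 0.15 with an estimated correlation).

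Serpinb3b (3.14 ± 0.644, adjusted p = 0.0283) and Defb3 rose among 29 wound keratinocyte genes in K14-OPN, also 2 adjusted over the list alone. All 29 fold changes were positive (median 1.89, camera 7.79e-14, and adjusted p = 0.317 with an estimated correlation). Of 30 cell cycle genes Rrm2 rose (1.88 ± 0.429, adjusted p = 0.0445), or 4 adjusted over the list alone, with 26 positive (camera 7.26e-06, and adjusted p = 0.15 with an estimated correlation). Lce1m (−4.59 ± 0.973, adjusted p = 0.0318) fell among 26 cornified envelope genes, or 9 fell and 1 rose adjusted over the list alone (camera 0.0119, and adjusted p = 0.589 with an estimated correlation). Dermal fibroblast genes were negative for 13 of 16 members (median −1.77), with none passing and 6 falling adjusted over the list alone (camera 0.00851, and adjusted p = 0.583 with an estimated correlation). Hair shaft genes were negative for 23 of 23 (median −7.36), with none passing and 23 adjusted over the list alone (camera 0.000148, and adjusted p = 0.589 with an estimated correlation). Without WT 10, K14-OPN 11 and OPN-null 9 these medians were −2.06 and 0.175 (camera 0.00015 and 0.0946). Ercc1 rose (2.53 ± 0.456, adjusted p = 0.0153), the 1 nucleotide excision repair gene to pass, also adjusted over the list alone. Of 18 macrophage genes 15 were positive and 1, Cd68, rose (3.08 ± 0.690, adjusted p = 0.0396), also 1 adjusted over the list alone. Of 27 interferon genes 23 were positive and none passed in either adjustment. Their camera adjusted p were 7.26e-06 and 9.07e-08, with adjusted p = 0.403 and 0.446 with an estimated correlation. Without the same 3 libraries their medians went from 0.855 to 0.279 and from 0.539 to −0.0463. That fit kept unirradiated K14-OPN 1, described next, and left fewer others of its group beside it. These medians are therefore not values without that library. One unirradiated library, K14-OPN 1, had a neutrophil gene mean of 5.42 log2 CPM against −1.26 to 1.22 in the other 7 unirradiated libraries. Its wound keratinocyte mean of 6.89 (2.41 to 4.32 in those 7) lay within the 5.6 to 8.34 of the irradiated libraries. Its interferon mean was 4.64 (−0.746 to 1.98) and its macrophage mean 4.55 (−0.604 to 2.57). Without it 790 genes were called in this comparison. The count was 74, 10 and 18 without K14-OPN UVB 1, 2 or 3 and 108 without unirradiated K14-OPN 11. In the Lars2-rich libraries alone 708 genes were called, 643 (90.8%) of them with the same sign in the 7SK-rich pair, against 65.4% of all genes.

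**Figure D3:**
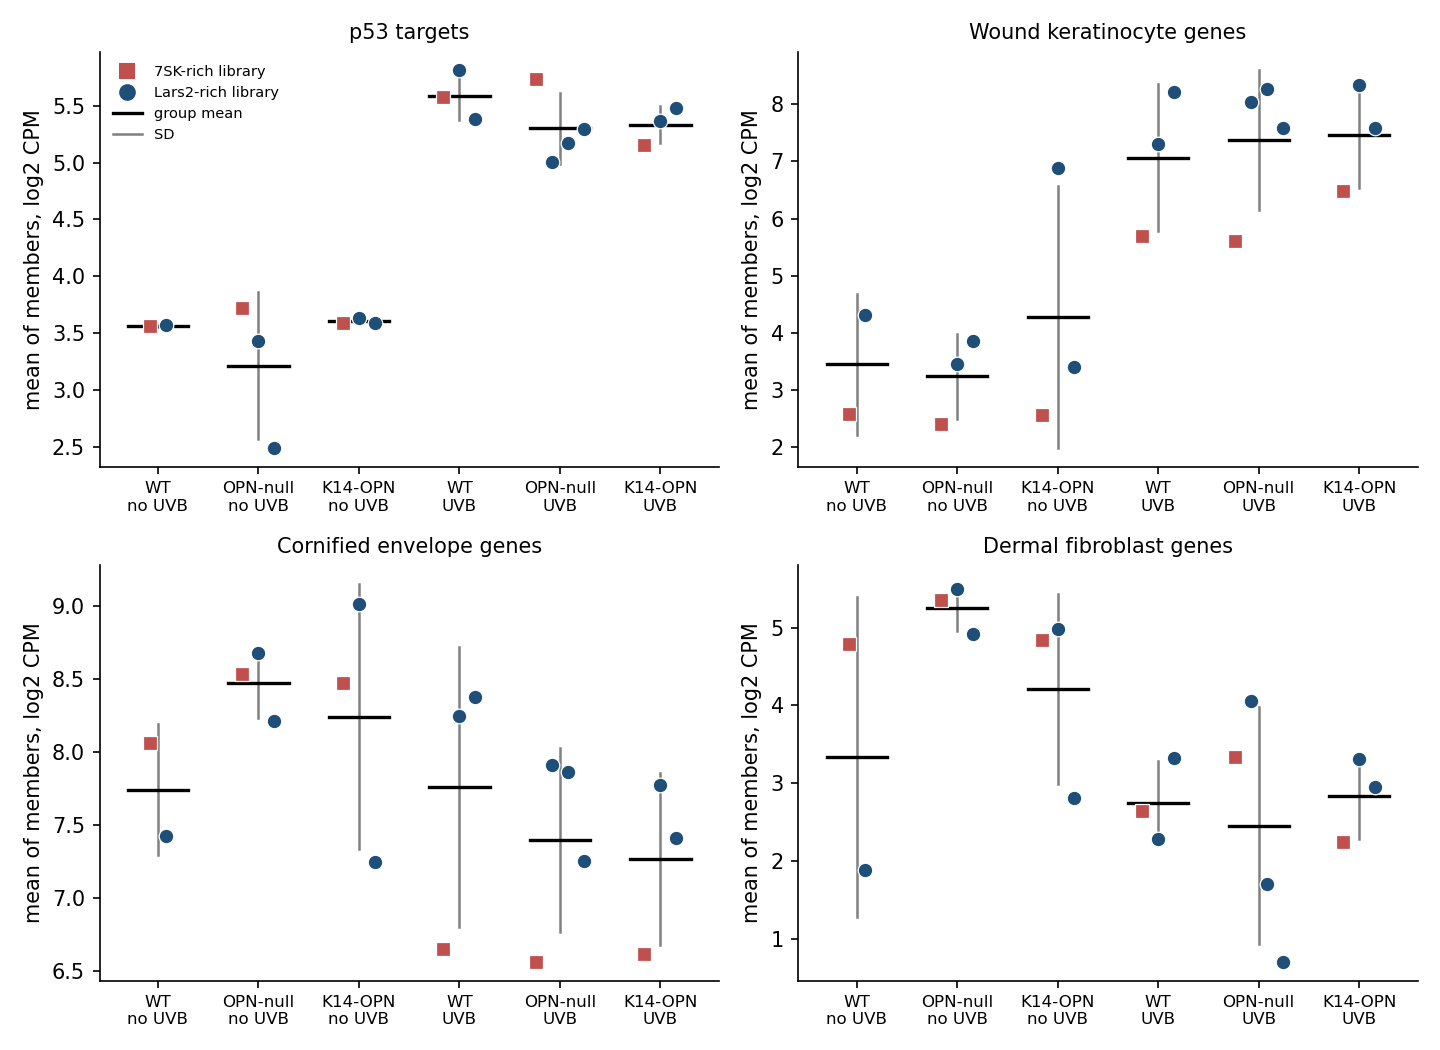
Mean log2 CPM of the p53 target, wound keratinocyte, cornified envelope and dermal fibroblast lists in each library, by genotype and UVB exposure. Squares are 7SK-rich and circles Lars2-rich libraries, with a black line at the group mean and a grey bar of 1 SD on each side. The p53 target means were 5 to 5.81 in the 10 irradiated libraries.

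After UVB, edgeR called 1 gene between WT and OPN-null, Pkd2 (chromosome 5, 104459450 to 104505819, plus strand), which encodes the cation channel polycystin 2 and starts downstream of Spp1 on the same strand. Pkd2 was at 2.47 ± 0.724 CPM (SD, n = 3) in WT and 23.1 ± 6.82 (n = 4) in OPN-null, a log2 fold change of −3.23 ± 0.455 (edgeR adjusted p = 0.0334). It was −3.06 in the 7SK-rich and −3.18 in the Lars2-rich libraries. Without UVB the values were 7.96 ± 4.58 CPM in WT (n = 2), 42.2 ± 9.19 in OPN-null (n = 3) and 34.9 ± 14.0 in K14-OPN (n = 3). K14-OPN was at 17.3 ± 3.38 after UVB (n = 3). It was the only one of 18 measured neighbours of Spp1 to pass, over all genes or adjusted over the list alone (adjusted p = 3.18e-05). Of 27 interferon response genes 26 were lower in WT, with a median of −2.14, none passing over all genes or adjusted over the list alone. Zbp1, a nucleic acid sensor, was at −2.75 ± 1.15 and Oasl2 at −3.27 ± 1.34 (adjusted p = 1 for each). The interferon and neutrophil lists were lower in camera (adjusted p = 3.4e-08 and 7e-05), and sterol synthesis genes, 18 of 20 positive, were higher (0.00233). With an estimated correlation their adjusted p were 0.742, 0.742 and 0.366. In edgeR 287 genes had an unadjusted p below 0.05, fewer than the 946 expected by chance, and with library kind as a term 899. Such a low count does not measure how alike the groups are. DESeq2 called 2 genes, Pkd2 and Spp1, and limma with quality weights 4 (these and C430019N01Rik and Gm43417). Pkd2 lost its call in edgeR without any 1 of the 7 libraries and in a fit of these 7 alone (460 genes at an unadjusted p below 0.05). These fits have fewer samples. Its CPM ranged from 1.74 to 3.19 in the irradiated WT and from 16.67 to 32.76 in the irradiated OPN-null libraries.

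**Figure D4:**
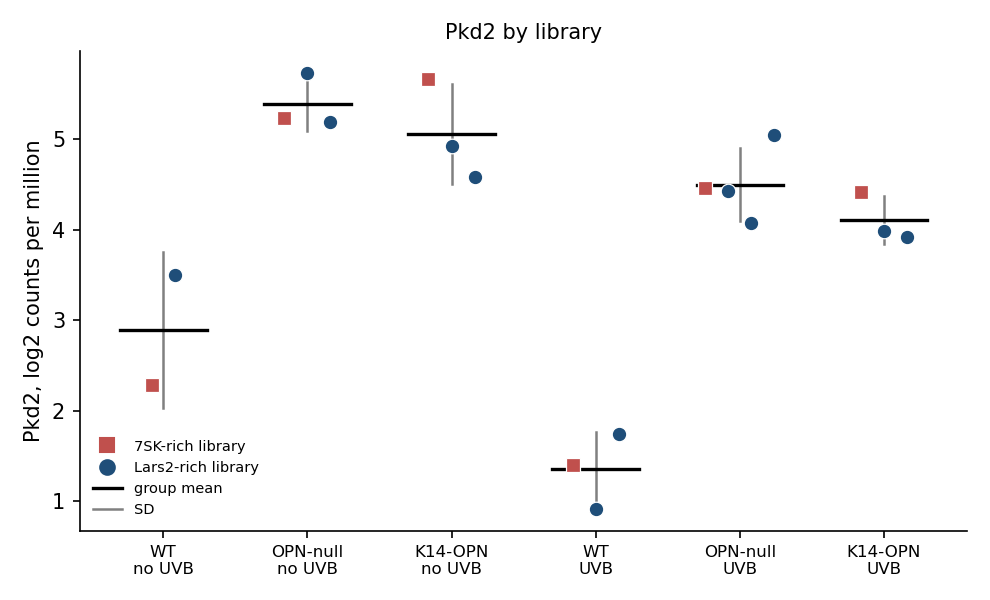
Pkd2 in each library as log2 CPM by genotype and UVB exposure. Squares are 7SK-rich and circles Lars2-rich libraries, with a black line at the group mean and a grey bar of 1 SD on each side. The 5 WT libraries lie between 0.918 and 3.50 and the other 13 between 3.92 and 5.73.

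K14-OPN and OPN-null after UVB differed in no gene by edgeR. An unadjusted p below 0.05 was found for 638 genes, and for 1731 with library kind as a term, against 946 expected by chance. DESeq2 called 4 (Psap, Cdk20, Trim2 and Spp1), limma with quality weights 1870 and edgeR without the filter 2 (Spp1 and Akr1c19). Macrophage genes were higher in K14-OPN for 16 of 18 members, with a median of 0.911. The arginase gene Arg1 was at 2.17 ± 0.499 (adjusted p = 1 over all genes, and 0.00773 adjusted over the list alone, the 1 member to pass) and the lysozyme gene Lyz2 at 1.99 ± 0.841. Interferon response genes were higher for 24 of 27 (median 0.699), with none passing over all genes or adjusted over the list alone. The macrophage and interferon lists were higher in camera (adjusted p = 1.22e-05 and 2.33e-06, and adjusted p = 0.902 for each with an estimated correlation). On simulated counts for this comparison, drawn without library kinds, the test recovered 0, 7.46 and 40.9% of genes changed by 2, 4 and 8-fold.

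Between K14-OPN and WT after UVB edgeR called no gene. An unadjusted p below 0.05 was found for 389 genes, and for 843 with library kind as a term, against 946 expected by chance. DESeq2 called 2 (Nos2 and Pkd2), limma with quality weights 774 and edgeR without the filter 5 (Slfn4, Csf3r, Oasl2, Cxcr4 and Akr1c19). All 27 interferon response genes were higher in K14-OPN, with a median of 2.79. Among them were Zbp1 (4.31 ± 1.26), Oasl2 (3.98 ± 1.42) and the transcription factor gene Irf7 (2.83 ± 1.04), and none passed adjusted over the list alone. All 18 macrophage genes were higher, with Lyz2 at 3.04 ± 0.968 and Arg1 at 1.95 ± 0.547, the 1 member to pass adjusted over the list alone (0.044). All 16 neutrophil genes were higher, with the receptor gene Csf3r at 3.97 ± 1.55 and none passing adjusted over the list alone. Camera gave adjusted p = 6.17e-26, 1.35e-15 and 2.05e-11 for these 3 lists, and adjusted p = 0.125, 0.125 and 0.202 with an estimated correlation. Pkd2 was higher in K14-OPN by 2.81 ± 0.459 (adjusted p = 0.215, and 0.000205 adjusted over the neighbours of Spp1 alone). As means per library, interferon genes differed by 2.53 log2 units (2.48 in 7SK-rich and 2.55 in Lars2-rich libraries; exact two-sided permutation p = 0.1, the smallest that 20 assignments give, adjusted p = 0.471 over 12 such tests). Macrophage genes differed by 2.03 (1.82 and 2.14; exact permutation p = 0.1, adjusted p = 0.471). In the other 10 of these tests the libraries overlapped, with exact permutation p = 0.3 for neutrophil and for cytokine genes here and 0.171 to 0.571 for the 4 lists against OPN-null. Erythrocyte genes were higher in K14-OPN than in WT for 5 of 6 members (median 1.55, none passing in either adjustment, camera 0.306). Their median was 0.817 in K14-OPN against OPN-null and −0.81 in WT against OPN-null.

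**Figure D5:**
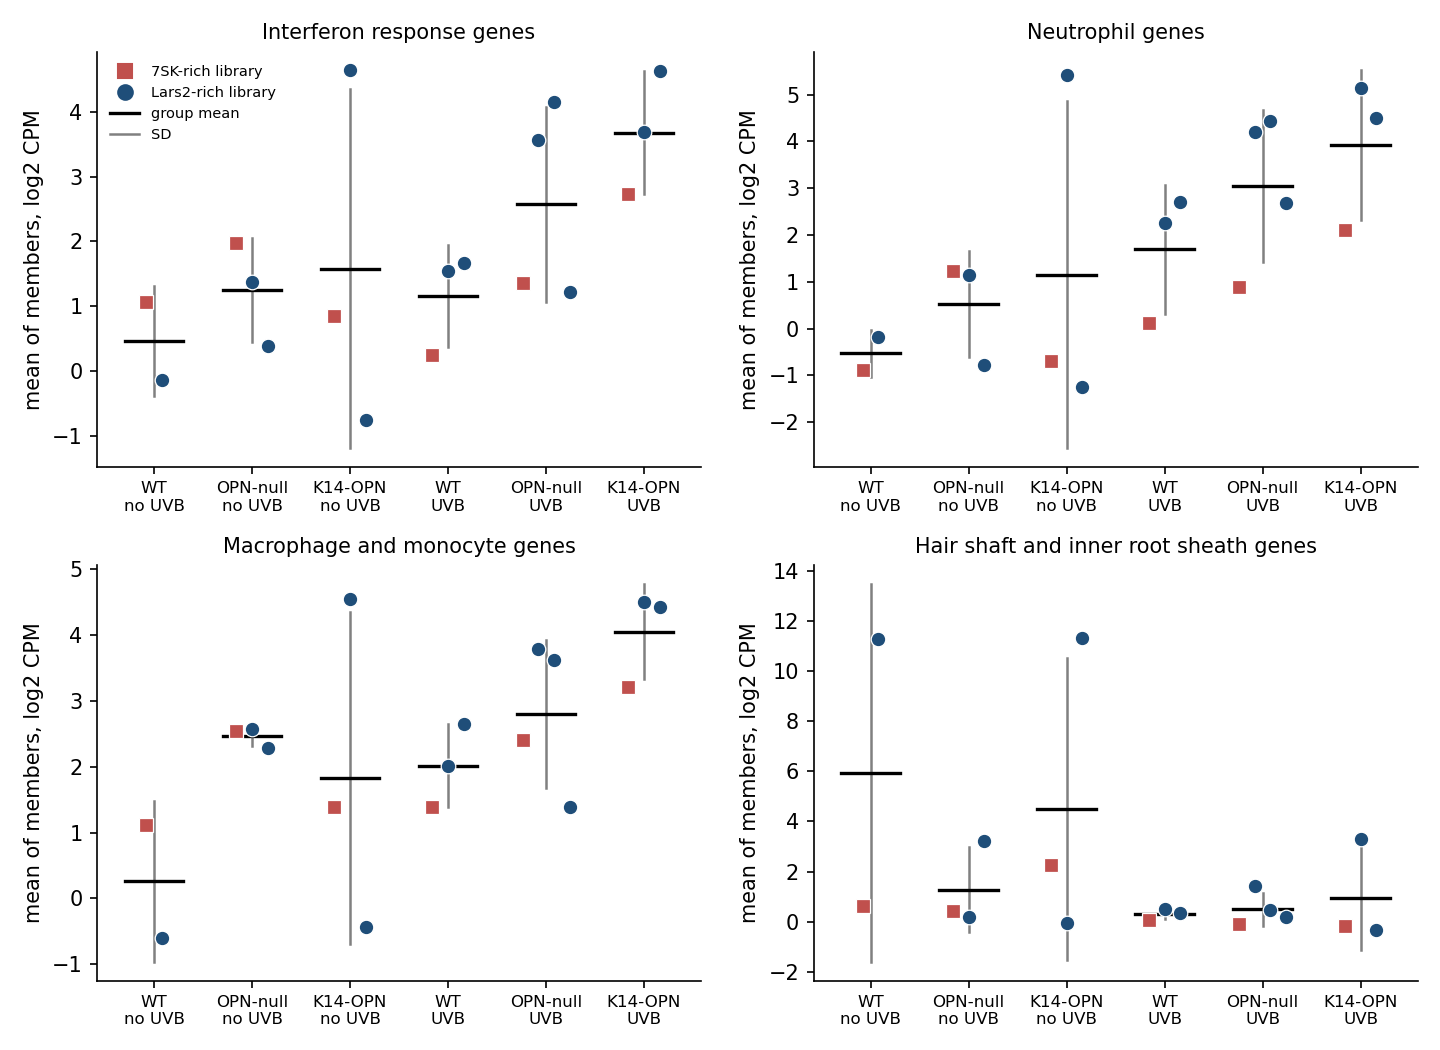
Mean log2 CPM of the interferon response, neutrophil, macrophage and hair shaft lists in each library, by genotype and UVB exposure. Squares are 7SK-rich and circles Lars2-rich libraries, with a black line at the group mean and a grey bar of 1 SD on each side. After UVB the interferon mean was 3.68 in K14-OPN, 2.57 in OPN-null and 1.15 in WT. Hair shaft genes were high in 2 unirradiated libraries, WT 10 and K14-OPN 11.

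Whether WT and K14-OPN differ from OPN-null in a similar way after UVB was examined across genes, which are not independent replicates. The fold changes of the 2 comparisons, fitted on all 18 libraries, correlated with r = 0.508. In a fit of the 10 irradiated libraries alone (16230 genes) r was 0.446 and the covariance 0.307. Because both comparisons use the same 4 OPN-null libraries, counts of all 10 irradiated libraries, controls included, were simulated 20 times with no difference between groups. In these r was 0.445 (0.430 to 0.474) and the covariance 0.276 (0.267 to 0.298). Genes were drawn independently, so these ranges leave out deviations that the genes of a library share. For the r of 0.508, from fits of all 18 libraries without each of the 10 irradiated ones in turn, the jackknife SD was 0.447. When the 4 control libraries were divided 2 and 2, in 6 ways, so that each comparison had its own, the median r was −0.0105 (−0.216 to 0.0535) and the median covariance −0.0144. In every division only 1 part held the 7SK-rich control, so library kind enters the 2 comparisons in opposite directions and can lower r here. With library kind as a term the covariance was 0.516 against 0.234 simulated, and with divided controls 0.109 (r = 0.0765, from −0.0385 to 0.222). No gene was called in both, and 198 had an unadjusted p below 0.05 in both with the same sign (30.5 expected of independent lists) and 29 with opposite signs, of 742 and 1247 in the 2 comparisons. The simulations had medians of 37 and 0, of 226.5 and 232, so the numbers are not directly comparable. With divided controls the medians were 52 with the same and 37.5 with opposite signs. In the fits that include the unirradiated libraries, r was 0.22 without K14-OPN UVB 1 and 0.83 without OPN-null UVB 16.

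Without UVB the genotypes differed in no gene by edgeR. WT against OPN-null had 847 genes at an unadjusted p below 0.05 (7 by DESeq2), K14-OPN against OPN-null 1118 (2 by DESeq2, Npy and Gm13822) and K14-OPN against WT 368 (12 by DESeq2). Limma with quality weights called 0 in each, and edgeR without the filter on low counts 246, 322 and 86. Hair shaft genes were higher than in OPN-null for 23 of 23 members in WT and in K14-OPN, with 23 and 21 passing adjusted over the list alone and none over all genes. Krt33a was at 10.11 ± 3.43 and 9.72 ± 3.34 (camera 2.04e-06 and 4.65e-06, and adjusted p = 0.585 and 0.81 with an estimated correlation). In WT 10 and K14-OPN 11 the mean of this list was 11.3 log2 CPM, against −0.316 to 3.29 in the other 16 libraries. Without these and OPN-null 9 the adjusted p were 0.542 and 0.116. Dermal fibroblast genes were lower in WT than in OPN-null for 15 of 16 members (camera 3.53e-10, and adjusted p = 0.347 with an estimated correlation), none passing in either adjustment. The same 2 libraries held the lowest values of that list without UVB, 1.88 to 2.81 log2 CPM against 4.79 to 5.50 in the other 6. In K14-OPN against WT, all 25 cytokine and chemokine genes and all 16 neutrophil genes were higher, with none passing in either adjustment (camera 0.00816 and 0.0375, and adjusted p = 0.816 for each with an estimated correlation). In K14-OPN 1 the cytokine mean was 5.85 log2 CPM, against −0.0108 to 2.33 in the other 7 unirradiated libraries. Macrophage genes in K14-OPN against OPN-null had a positive median and mean (0.224 and 0.531) and a lower rank in camera (adjusted p = 0.00293, and adjusted p = 0.81 with an estimated correlation). Of 15 genes called between WT and OPN-null in the Lars2-rich libraries 3 (20%) had the same sign in the 7SK-rich pair, against 41.7% of all genes. The WT side of these calls was 1 library, WT 10. Of 42 between K14-OPN and OPN-null 7 (16.7%) had the same sign, against 42.4% of all genes.

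Tests of whether the UVB response itself differed between genotypes called no gene by edgeR, with 488 genes at an unadjusted p below 0.05 for WT against OPN-null and 729 for K14-OPN against OPN-null. DESeq2 called 4 (Npy, Stfa2l1, Gm14039 and Gm11956) and 2 (Npy and Gm13822), limma with quality weights 0 and 0, and edgeR without the filter 149 and 140. The UVB response of Spp1 exceeded that of OPN-null by 2.75 ± 1.57 in WT and 2.63 ± 1.44 in K14-OPN (adjusted p = 1 for each). The UVB response of WT minus that of OPN-null was positive for 21 of 26 cornified envelope genes (median 1.38) and 14 of 16 dermal fibroblast genes (median 1.15), both with camera adjusted p = 2.54e-07 and adjusted p = 0.601 with an estimated correlation. The dermal mean without UVB was 3.33 ± 2.06 log2 CPM in WT (SD, n = 2; 1.88 in WT 10) and 5.26 in OPN-null, while after UVB the median difference between them was −0.241. Without WT 10, K14-OPN 11 and OPN-null 9 the 2 medians were 1.11 and 0.7 (camera 2.7e-06 and 0.00386). Sterol synthesis genes were 16 of 20 positive (median 0.64, camera 2.24e-05, and adjusted p = 0.0676 with an estimated correlation).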

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

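All tests of explanations for Pkd2 other than the count of neighbours, and for unirradiated K14-OPN 1 and the hair genes other than the growing follicle genes, were chosen after the result was seen; the counts over other splits of the samples were planned, except those over splits balanced by library kind.

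Pkd2 was lower in all 5 WT libraries than in the other 13, on average by 2.77 log2 units (difference −2.772, not tested, since the gene was singled out for this difference). Library kind as the cause is argued against by the difference after UVB of −3.06 in the 7SK-rich pair. In the annotation used here Spp1 ends at 104441050 and Pkd2 starts at 104459450, so the 2 genes do not overlap. This argues against reads of Pkd2 counted for Spp1, although the annotation release behind the counts is not given. Spp1 was below the Pkd2 CPM missing against the OPN-null mean in 2 of the 5 WT libraries, both 7SK-rich, and above it in the other 3. That count alone could not tell. A segment that shifts many neighbours stays open. Of 17 other measured neighbours 1, Abcg3, had an unadjusted p below 0.05, but so few of all genes did in this comparison (287 of 18910) that the count decides nothing. A further open hypothesis, found on these data, is that the allele or flanking segment shared by OPN-null and K14-OPN may raise Pkd2, since Pkd2 was higher in both than in WT with and without UVB, by 2.16 or more.

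Unirradiated K14-OPN 1 had wound keratinocyte genes at a mean of 6.89 log2 CPM (2.41 to 4.32 in the other 7 unirradiated libraries), with neutrophil, interferon, macrophage and cytokine genes also above the range of those 7. An irradiated library under the wrong label is argued against by its p53 target mean of 3.628, inside 2.49 to 3.72 of the other unirradiated libraries and below 5 to 5.81 of the irradiated ones. Library kind is argued against by a neutrophil mean 4.28 above the next unirradiated Lars2-rich library. Blood stays open as a source of the immune genes, since the erythrocyte mean of 3.27 lay 1.38 above the highest of the other 7 unirradiated libraries (0.875 to 1.89). A wound or local inflammation in this skin sample, which may account for the pattern, also stays open and was not tested. Blood was not tested as a source of the wound list, whose members were chosen as keratinocyte genes.

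Hair shaft genes (mean 11.3 log2 CPM) and melanocyte genes (3.78 to 4.00) were high in unirradiated WT 10 and K14-OPN 11, against −0.316 to 3.29 and −1.79 to −0.253 in the other 16 libraries. Dermal fibroblast genes were lower in both than in the other 6 unirradiated libraries, but so were basal keratinocyte genes (5.94 and 6.46 against 7.56 to 7.87), which hair genes taking more of the counts would also give. Relative to basal keratinocyte genes, the dermal mean was −4.58 in WT 10, −3.14 in K14-OPN 11 and −2.89 to −2.06 in the other 6 (SD 0.322). More dermis in the scraping is argued against in WT 10 (−1.7 from the lowest of the 6) and stays open in K14-OPN 11 (−0.248, less than that SD). Library kind is argued against by hair shaft means at least 7.97 above the other 10 Lars2-rich libraries. Growing hair follicles in the sample also remain as a hypothesis: 5 of 6 genes of the growing follicle (Shh, Lef1, Fgf5, Msx1 and Ovol1, not Lgr5) were higher in both libraries than in the other 6, which is consistent with skin in a growth phase of the hair cycle.

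In the UVB response of WT against that of OPN-null, 11 lists differed in camera at the preset correlation. Higher in WT were cornified envelope and dermal fibroblast genes (adjusted p = 2.54e-07 for each), early suprabasal and sterol synthesis genes (2.24e-05 for each), macrophage genes (0.0101), Langerhans and dendritic cell genes (0.0119), barrier lipid genes (0.012), basal keratinocyte genes (0.019) and circadian clock genes (0.0488). Lower were hair shaft (0.000305) and melanocyte genes (0.0498). With an estimated correlation their adjusted p were 0.0676 for sterol synthesis and 0.353 to 0.878 for the others. Without WT 10, K14-OPN 11 and OPN-null 9 the adjusted p were 2.7e-06 for cornified envelope and 0.00386 for dermal fibroblast genes, but 0.805 for hair shaft, 0.675 for melanocyte, 0.291 for macrophage and 0.939 for basal keratinocyte genes.

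In the UVB response of K14-OPN against that of OPN-null, 8 lists differed at the preset correlation: macrophage (adjusted p = 3.89e-07), interferon (2.74e-05), dermal fibroblast (0.000706), basal keratinocyte (0.00121), Langerhans and dendritic cell (0.00561), neutrophil (0.0144) and sterol synthesis genes (0.0342) higher, and hair shaft genes (0.00338) lower. With an estimated correlation the adjusted p was 0.706 for each. The interferon and neutrophil lists differ in sign between measures: the interferon median was −0.293 and its mean −0.979, and the neutrophil median was −2.16, while camera ranked both higher. Leaving out WT 10, K14-OPN 11 and OPN-null 9 kept unirradiated K14-OPN 1, in which immune genes were high, with fewer others of its group beside it. Without the 3 libraries the adjusted p were 0.000264 for macrophage (whose median went from 0.641 to −0.0927), 0.0106 for interferon, 0.00416 for dermal fibroblast and 0.0406 for basal keratinocyte genes, but 0.299 for neutrophil and 0.169 for hair shaft genes.

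In the 4 irradiated OPN-null libraries, 1 library stood far from the others in 6 of 123 values. Library 16, the 7SK-rich one, was low in Krt6b (gap over range 0.866), Ccl20 (0.859), Areg (0.869), Hbegf (0.931) and the mitochondrially encoded list (0.897), and library 14 was low in Ercc5 (0.858). Chance flags about 1 in 20 groups, which for 123 values is 6.15.

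Other splits of the same libraries were counted for each comparison of groups of 3 or more. Over all splits, the share that reached the real number of genes was below 0.05 in 2 comparisons. These were the UVB response of OPN-null (1 of 35 splits, 644 genes against at most 0 in another split) and WT against OPN-null after UVB (1 of 35, 1 gene against 0). Only 20 of these 35 splits have 1 7SK-rich library in each group, as the real groups do, and among 20 the smallest share is 0.05, too few to exclude chance. The 1 gene, Pkd2, also lost its call without any 1 of the 7 libraries, in fits of fewer samples. Its CPM after UVB ranged from 1.74 to 3.19 in WT and from 16.67 to 32.76 in OPN-null. Chance cannot be excluded for the lists in those comparisons (3 of 35, 13 lists against 13, and 15 of 35, 8 against 17), nor for K14-OPN against OPN-null after UVB (35 of 35, 0 genes against 0, and 19 of 35, 7 lists against 15). The same holds for the difference of the UVB response of K14-OPN and OPN-null (50 of 50 drawn splits, 0 genes against 1, and 36 of 50, 8 lists against 20) and for the covariance of WT and K14-OPN against OPN-null after UVB (19 of 40, 0.307 against 2.019). Those 40 assignments were drawn without regard to library kind. They need not hold 1 7SK-rich library in each group, which can enlarge their covariance. The designs of 3 against 3 have too few splits for a share below 0.05: 200 genes against 0 and 18 lists against 17 in the UVB response of K14-OPN (1 of 10 for each), 0 genes against 0 and 13 lists against 15 for K14-OPN against WT after UVB (10 and 2 of 10), and 0 genes against 1 and 7 lists against 18 for K14-OPN against OPN-null without UVB (10 and 9 of 10). Some other splits called more than 2 times the real number of lists at the preset correlation, and what these splits share was not tested.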

How the results depend on the processing

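Library kind as a term, the Lars2-rich libraries alone and the fits without 3 outlying libraries were chosen after seeing the data, and the other alternatives were planned. Where a value moved, the cause was not tested, except that fits without a library or of fewer libraries have fewer samples. RLE scaling kept each count of called genes within 1.5 times. With an estimated correlation the lists called in the UVB responses of WT, OPN-null and K14-OPN numbered 1, 0 and 0, against 14, 13 and 18 at the preset value. The limma test fry, not among the alternatives listed as fixed in advance, called 2, 6 and 9 lists there and 0 in each other contrast. It allows for correlation between genes but asks whether a list changed at all, not whether it changed more than other genes. Of 2477 values of 150 named gene and comparison pairs other than those of Spp1, 1798 stayed on the same side of the threshold, 603 lost the call, 72 gained it and 4 changed sign, all of Krt33a. Without UVB, Krt33a against OPN-null in WT was −0.10 without the outlying libraries, −0.12 with library kind in addition and −2.31 without WT 10, and in K14-OPN −0.88 without K14-OPN 11.

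The UVB response of WT, 18 genes, became 883 with DESeq2, 643 without the filter, 0 with the compared groups only, 37 with the dermal covariate, 921 with quality weights, 705 with library kind, 0 in the Lars2-rich libraries, 1 without the 3 outlying libraries, 760 without them and with library kind, and 0 to 0 with each library left out. That of OPN-null, 644 genes, became 2347, 1219 without the filter, 25 with the dermal covariate, 2320 with quality weights, 2594 with library kind, 1913 in the Lars2-rich libraries, 2926 without the outlying libraries and with library kind, and 200 to 679 with each library left out. That of K14-OPN, 200 genes, became 1371, 844 without the filter, 0 with the compared groups only, 316 with the dermal covariate, 1424 with quality weights, 1458 with library kind, 708 in the Lars2-rich libraries, 352 without the outlying libraries, 2174 with library kind in addition, and 10 to 790 with each library left out. With the compared groups only and the replicate block it was also 0, so this 0 says nothing of the block. The K14-OPN libraries share only the numbers 1 and 2, whose deviations from the group means correlated at −0.451 and −0.578. Both are pairs of a 7SK-rich and a Lars2-rich library, so these values cannot show whether the numbers pair samples.

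After UVB, WT against OPN-null (1 gene) gave 2 with DESeq2 and 2 without the filter (Spp1 and Pkd2 in both), 0 with the compared groups only or the dermal covariate, 4 with quality weights (Spp1, Pkd2, C430019N01Rik and Gm43417), 2 in the Lars2-rich libraries (Spp1 and Gm43417), 2 without the outlying libraries and with library kind (Spp1 and Pkd2), and 0 to 0 with each library left out. K14-OPN against OPN-null (0) gave 4 with DESeq2, 2 without the filter (Spp1 and Akr1c19), 1870 with quality weights, 1 in the Lars2-rich libraries (Spp1) and 20 without the outlying libraries and with library kind. K14-OPN against WT (0) gave 2 with DESeq2, 5 without the filter (Slfn4, Csf3r, Oasl2, Cxcr4 and Akr1c19), 774 with quality weights and 2 without the outlying libraries and with library kind (Pkd2 and Krt84). Without UVB, WT against OPN-null (0) gave 7 with DESeq2, 246 without the filter, 15 in the Lars2-rich libraries and 0 to 1 with each library left out (Exosc9, without OPN-null 10). K14-OPN against OPN-null (0) gave 2 with DESeq2, 322 without the filter, 42 in the Lars2-rich libraries and 0 to 2 with each library left out (Exosc9 and Prss12). K14-OPN against WT (0) gave 12 with DESeq2 and 86 without the filter. The differences of the UVB response from OPN-null (0 each) gave 4 with DESeq2 and 149 without the filter for WT, and 2 and 140 for K14-OPN.

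The UVB response of Spp1 passed over all genes in WT without the filter (3.22), with quality weights (5.78) and without the outlying libraries with library kind (6.07), and in K14-OPN with DESeq2 (3.08), without the filter (3.12) and in the Lars2-rich libraries (2.90). In OPN-null it was −0.59 with the dermal covariate, −0.23 without the outlying libraries with library kind, and −0.20 (without OPN-null UVB 14) to 1.2 with each library left out. After UVB, Spp1 against OPN-null passed in WT with DESeq2 (5.97), without the filter (5.99), with quality weights (6.09), in the Lars2-rich libraries (6.36) and without the outlying libraries with library kind (6.01), and in K14-OPN likewise (7.09, 7.12, 6.69, 6.42 and 7.32). Without UVB it passed without the filter in WT (3.30) and K14-OPN (4.53), and in WT it was −0.33 without the outlying libraries, −0.29 with library kind in addition, and 0.08 to 4.19 with each library left out. The similarity r was 0.22 to 0.83 with each library left out and 0.67 in the Lars2-rich libraries. The covariance, 0.534 in the fit of all 18 libraries, was 0.336 without K14-OPN UVB 1 and 2.41 without OPN-null UVB 16, its range with each library left out. In the Lars2-rich libraries it was 1.81. On simulated counts without library kinds, the planned model recovered 8-fold changes at 4.55 to 40.9%. With the spread found with library kind as a term it recovered 59.1 to 78.8%.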

Other observations

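No test in this part was chosen after its result was seen, but which lists to describe here was. The UVB response of OPN-null was not described above for osteopontin receptor, sebaceous, hair follicle stem cell and lipid genes. In OPN-null after UVB, Itgb1 (1.58 ± 0.421, adjusted p = 0.0479) and Itgb6 (2.15 ± 0.556, 0.0432) rose among 11 integrin and other osteopontin receptor genes, with 4 rising and 1 falling adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.129). In the hair follicle stem cell list Lgr6, a marker of stem cells of the upper follicle, changed by −4.26 ± 0.864 (adjusted p = 0.0152) and Cd34, a marker of bulge cells, by −2.44 ± 0.617 (0.0386), 2 of 13 members, or 3 falling and 1 rising adjusted over the list alone (camera 0.0926). The desaturase gene Scd1 of sebaceous glands changed by −3.19 ± 0.593 (adjusted p = 0.00933), 1 of 14 members by either adjustment (camera 0.201). Among barrier lipid genes the ceramide synthase gene Cers3 rose by 1.54 ± 0.412 (adjusted p = 0.0481) and the ceramidase gene Acer1 changed by −1.93 ± 0.372 (0.0114), 2 of 20 members, or 3 rising and 2 falling adjusted over the list alone, and the list did not pass (camera 0.441). Of 20 sterol synthesis genes Fdps fell (−1.81 ± 0.385, adjusted p = 0.0175), or 4 adjusted over the list alone (camera 0.0216, and adjusted p = 0.411 with an estimated correlation).

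Within the lists of stress genes, the chaperone gene Dnajb9 rose in OPN-null after UVB (2.71 ± 0.692, adjusted p = 0.0408) and Herpud1 fell (−1.39 ± 0.294, 0.0175), 2 of 18 members, or 2 rising and 1 falling adjusted over the list alone (camera 0.00589, and adjusted p = 0.495 with an estimated correlation). Of 18 NRF2 antioxidant genes the aldo-keto reductase gene Akr1b8 rose (4.55 ± 1.08, adjusted p = 0.0296), or 3 rose and 2 fell adjusted over the list alone (camera 0.0707). Basal keratinocyte genes moved both ways in OPN-null, Itgb1 rising and Krt15, a keratin of quiescent basal and bulge cells, changing by −2.91 ± 0.699 (adjusted p = 0.031), or 5 rising and 1 falling adjusted over the list alone (camera 0.0065, and adjusted p = 0.495 with an estimated correlation). Of 30 cell cycle genes Rrm2 (1.64 ± 0.413, adjusted p = 0.0375) and Mcm4 (1.56 ± 0.400, 0.0413) rose, or 3 adjusted over the list alone (camera 0.00594, and adjusted p = 0.45 with an estimated correlation). The mitochondrially encoded list had means of 5.51 to 7.01 log2 CPM in the 7SK-rich and 7.97 to 10.1 in the Lars2-rich libraries.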
